A study of Sus scrofa with 16 samples.

How the data were processed

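Single-nucleus RNA was counted in 5 libraries and spatial RNA in 11 Visium sections of Sus scrofa. The deposited matrices hold UMI counts per gene and barcode, whole numbers that are neither normalised nor log-transformed per the file headers. A deposited table for each section holds a score per gene, Moran's I over the spots under tissue, per the file headers. Cell Ranger 7.0.1, Space Ranger and Seurat were used per the submitters' processing notes, and the genome build is not given in the sources used here. Per the file names, cellbender called the cell barcodes of the nuclei and vireo assigned the nuclei of the 3 pooled libraries to donors, with and without donor genotypes. Per the labels' protocols, frozen flask cells and 25 µm sections of the seeded scaffold went through the same nuclei isolation kit.

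Genes were joined by Ensembl identifier, 22040 in all, of which 15865 had a symbol in at least 1 of 2 versions of the features files. With a reference table of gene names for the others, 15933 could be printed with a symbol. The 2 versions differ in symbols and order, and 4 sections carry 1 version and 7 the other. Counts of closely related copies, such as keratins, myosin heavy chains, globins and S100 genes, are uncertain where reads could belong to either copy.

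Nuclei were kept if cellbender called them cells, if they were in the filtered matrix, and if they had at least 500 UMIs and at most 5% mitochondrially encoded UMIs. Pooled nuclei also had to be singlets by the genotype-based vireo calls, whose donor names were matched to animals by the descriptions of the spatial sections. Which nuclei of a pool are pre and which are post rests on this match and on the animals and conditions in the pool's title. Of 22119, 18918 and 23342 filtered barcodes in the 3 pools, 13218, 10154 and 10801 were unassigned by these calls. Nuclei assigned to a donor by both kinds of call had the same donor in 99.7%, 99.6% and 99.9% of cases. The uncorrected counts were used throughout, summed over the nuclei of each animal and condition into 4 pre and 4 post profiles, or over all spots under tissue of each section. Profiles and sections were checked for duplicates, and none was found among 28 and 55 pairs, where the lowest chi-square per degree of freedom was 67.9 and 19.2.

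The comparisons, tests, gene groups, cell type markers, naming rule for genes and most alternatives were chosen before the data were examined. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3, and DESeq2 1.42.0 was the alternative. CPM are TMM-scaled in the comparisons and plain in single sections. The 6-month and 3-month contrasts came from 1 fit of native, 3-month and 6-month sections. The gene groups were 21 for nuclei and 23 for sections. Each was set against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative, adjusted over the groups. The groups were also tested with fry of limma, which asks whether a group changed at all and not whether it differs from other genes. Shares, ratios, spot percentages and medians of Moran's I were compared by 2-sided exact permutation of profiles (70 labelings of 4 against 4) or sections (210 labelings of 6 against 4), adjusted within each family. Shares and ratios were taken on the log2 scale with 0.5 UMIs added. A spot was called bearing a tissue's RNA when at least 2% of its UMIs came from that tissue's genes, among spots of at least 500 UMIs, and between 0% and 7.24% of a section's spots lay from 1.5% to 2.5% in the skeletal muscle group.

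For nuclei, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 were used (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15). A cluster was named when at least 3 markers of a cell type were 2 times higher than in other nuclei and detected in at least 10% of its nuclei, with at least 1 marker among its 10 highest genes. These limits were set after the clusters were seen. Proliferating nuclei were counted after thinning each nucleus to 1000 UMIs, which left out 3.56% of post C nuclei and none elsewhere.

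Named genes have an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean log2 CPM of at least 4, a symbol and no overlap between groups. The 10 largest rises and 10 largest falls are named for the post against pre and the grafts against native comparison, and 5 of each for other contrasts, with the 2 members of each gene group with the smallest p. For the single pre-implant and 1-month sections, the 5 highest and 5 lowest ratios to the native mean are named among genes with at least 50 UMIs in the section or in every native section. Intervals for single sections are 95% Poisson intervals for CPM, Wilson intervals for shares of UMIs and exact binomial intervals for shares of nuclei, and a count of 0 was read as allowing 3 counts.

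Both conditions of the nuclei come from the same 4 animals, so pairing by animal follows from the design. Deviations from the group means correlated at 0.33, 0.36, −0.01 and 0.18 across genes within animals A, C, D and F, and at 0.26, 0.35 and 0.35 between the profiles that shared a pool. Genes are not independent replicates in these values. The tests were also run on simulated data with 200 changed genes. For the nuclei, edgeR recovered 1% of 2-fold and 27% of 4-fold changes among 15157 genes and called 2 unchanged genes, while DESeq2 recovered 15% and 69% and called 36. For grafts against native sections edgeR recovered 1% and 58% among 12196 genes and called 8 unchanged genes, and DESeq2 15% and 84% with 38.

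Alternatives covered scaling, filters, thresholds, thinning, donor calls, doublet scores, leaving out each profile or section, animal and pool blocks, and the annotation version as a covariate. Images, raw barcode matrices beyond a check of free RNA, and corrected counts of the nuclei other than as an alternative for C were not used here. A few results for single genes are not reported here. Figures were drawn with matplotlib 3.10.9.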

Results

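RNA molecules were counted in 16 pig samples, 5 single-nucleus RNA libraries and 11 Visium tissue sections, in which barcoded spots under a section record where each RNA lay. The nuclei came from cells taken from the abdominal muscle of minipigs, mesoangioblasts (vessel-associated progenitors that can form skeletal muscle) and fibroblasts mixed 7 to 3. They were sampled in flask culture before seeding (pre) and after 7 days on a decellularised pig oesophagus in a dynamic bioreactor (post), from animals A, C, D and F, which makes 4 pre and 4 post profiles. Of the 5 libraries, 3 each pooled the pre profile of one animal with the post profile of another (pre A with post D, pre D with post F, pre F with post A). The sections were native oesophagus (3 domestic pigs, numbered 1 to 3, and minipig C), an engineered graft of animal C before implantation, and grafts recovered after 1 month (D), 3 months (E and F) and 6 months (A, B and C).

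Depth differed between the profiles and between the sections. The pre profiles held 6071 nuclei in A, 2729 in C, 5793 in D and 7856 in F, with 51534728, 57623310, 61210421 and 68389996 UMIs in all (UMIs are counted RNA molecules). The post profiles of A, C, D and F held 3125, 5507, 1412 and 1846 nuclei with 11325256, 30919080, 5657031 and 9728379 UMIs. Median UMIs per nucleus were 6858, 19347, 8270 and 6393 before and 3231, 5046, 3510 and 3785 after the bioreactor. Mitochondrially encoded RNA made up 2.57%, 1.17%, 1.90% and 1.95% of the UMIs before and 0.802%, 0.485%, 2.06% and 1.24% after it. The native sections 1, 2, 3 and C held 21360857, 6306228, 11672280 and 2892378 UMIs, and the pre-implant section 13139399. The grafts of D, E, F, A, B and C held 4749132, 1584084, 8153107, 5761211, 7521127 and 15473768 UMIs. The shallowest sections were the E graft, with a median of 194 UMIs per spot, and native C, with 447, while the others had medians between 1372 and 5910.

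The first comparison asks how the seeded cells changed in the bioreactor. Genes of cell division stood lower after it. ASPM, which organises the mitotic spindle, fell from 58.5 ± 13.3 to 13.5 ± 9.10 counts scaled to a common depth (CPM; SD, n = 4 and 4), NCAPG2 of the condensin complex from 42.2 ± 11.5 to 11.3 ± 5.62, and CDC25C, the phosphatase that starts mitosis, from 24.4 ± 4.04 to 7.44 ± 3.30. STAC, an adaptor protein of calcium channels, rose from 27.7 ± 5.12 to 1334 ± 736.5 CPM, and PRR16, a regulator of cell size, from 4.68 ± 0.147 to 382 ± 191. TRPA1, an ion channel opened by irritants, rose from 21.1 ± 10.3 to 466 ± 439 CPM. EGLN3, an oxygen-sensing hydroxylase induced in hypoxia, rose from 4.63 ± 2.03 to 172 ± 242.

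Across 15157 genes, edgeR's quasi-likelihood test called 347 changed after Benjamini-Hochberg adjustment, 318 higher and 29 lower after the bioreactor. An unadjusted p under 0.05 was found for 4822 genes. The groups did not overlap for 3782 genes, where chance alone gives 2.86% of genes. The largest rises were SGPP2 (log2 fold change 7.50 ± 1.25 SE, adjusted p 0.0241), a phosphatase of sphingosine phosphate, PRR16 (6.35 ± 0.45, adjusted p 0.00112) and CGNL1 (5.82 ± 0.90, adjusted p 0.0218), a protein of cell junctions. They were followed by NMNAT3, STAC, EGLN3, PTPRT, PRICKLE2, TRPA1 and ARRDC4, at log2 fold changes of 5.67 down to 4.42 and adjusted p of 0.00868 to 0.0497. SGPP2, CGNL1, EGLN3 and PTPRT were among the 10 leading genes of a cluster of nuclei that was 99.98% post C. PRR16, PRICKLE2 and TRPA1 were among those of a cluster that was 97.58% post A. The naming rule required no overlap between groups, so all of these genes stood higher in every post profile than in any pre profile. This lack of overlap does not show how far 1 animal drove a rise. The largest falls were ADAMTS20 (log2 fold change −2.16 ± 0.43, adjusted p 0.0401), a matrix protease, and ASPM (−2.12 ± 0.44, adjusted p 0.0446). The other falls named were NCAPG2, AMOTL2, CCNB3, PSAT1 of serine synthesis, CHRDL1, VGLL3, SEMA3D and CDC25C, at −1.91 to −1.72 and adjusted p of 0.0221 to 0.0462. Fitted with animal as a block, which pairs each post profile with the pre profile of its animal, 5 genes passed, all higher, and 4 of them were among the 347. PRR16 stayed past the threshold (adjusted p 0.0315), and of the other genes named here STAC, ASPM and EGLN3 stood at 0.0613, 0.0613 and 0.102. DESeq2 called 2628 genes (1545 higher, 1083 lower).

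The count rested on single profiles. edgeR called 9, 3, 21 and 1 genes without pre A, C, D or F, 15 and 207 without post A or C, 1015 without post F, and 44 without both profiles of C. Genes at least 3 times higher in one pre profile than in the other pre profiles were also high in the post profile that shared its pool. There they kept 53.7% of that level for pre A (26 genes), 71.2% for pre D (9 genes) and 36.4% for pre F (4 genes), against 19.8%, 28.6% and 32.6% in the post profile of the same animal.

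**Figure D1:**
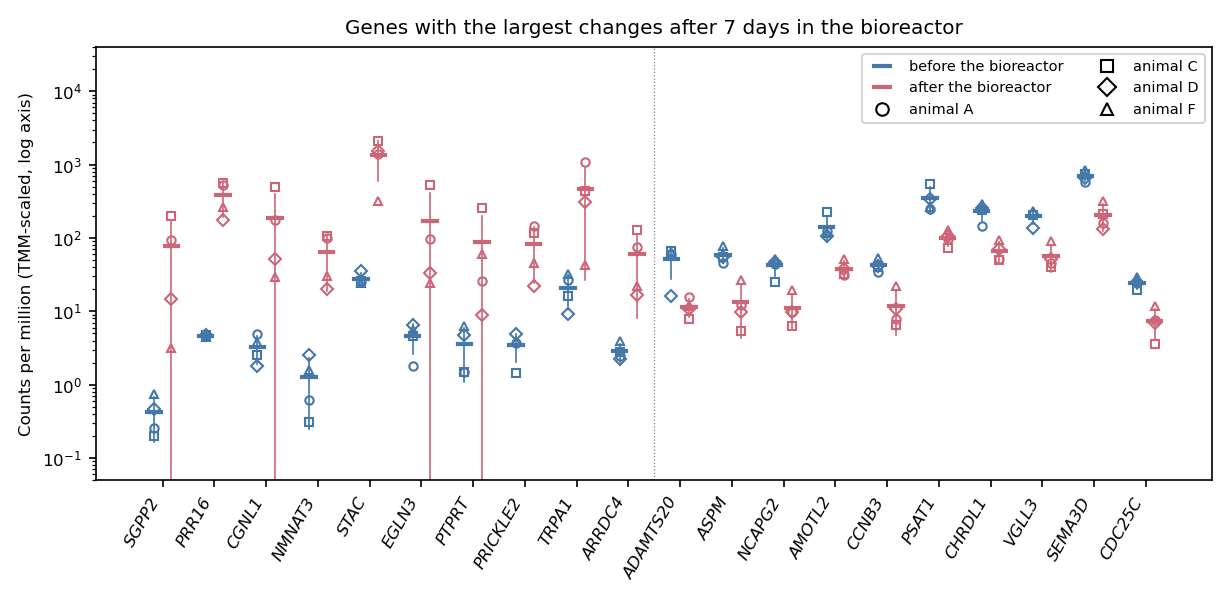
CPM on a log axis of the 10 genes with the largest rises and the 10 with the largest falls after the bioreactor, in the 4 pre and 4 post profiles. Points are profiles and lines are means ± SD, drawn to the axis where the SD exceeds the mean. The pre and post points of each gene do not overlap, as the naming rule required. STAC, for example, stood at 27.7 ± 5.12 against 1334 ± 736.5.

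The single-gene calls in the gene groups of the nuclei come from the unpaired fit. With animal as a block 5 genes passed, all higher. No fall of a gene in these groups therefore kept its call, and at most 4 rises did. Among the gene groups, all 29 measured proliferation genes had log2 fold changes below 0, with a median of −1.54. ASPM and MCM5 of the DNA replication helicase (log2 fold change −1.21, adjusted p 0.0440) fell, the other 27 did not pass, and 26 fell when adjusted over the list alone, among them TOP2A, BUB1 and RRM2. Limma's camera test placed the group below other genes (adjusted p = 3.5e-13; adjusted p = 0.434 with an estimated correlation). All 16 cholesterol synthesis genes were below 0 too (median −1.37), none passed singly and 8 fell when adjusted over the list alone, among them HMGCS1 at −1.39 (adjusted p 0.0868). This group lay below other genes (adjusted p = 4.2e-06; adjusted p = 0.434 with an estimated correlation). Of 16 contractile genes of smooth muscle and myofibroblasts, 14 were below 0 (median −1.32). None passed and 3 fell when adjusted over the list alone, MYLK and the matricellular genes CCN1 (−2.17, adjusted p 0.0533) and CCN2 (−2.55, adjusted p 0.0616). The contractile group lay below other genes (adjusted p = 3.0e-04; adjusted p = 0.434 with an estimated correlation).

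Inflammatory mediators moved the other way, with 19 of 21 above 0 and a median of 2.59. CXCL12, a chemokine, rose 3.36 on the log2 scale (adjusted p 0.0134) and complement C3 rose 4.20 (adjusted p 0.0184), 19 did not pass, and 8 rose when adjusted over the list alone, IL6, LIF and SOD2 among them. The group lay above other genes (adjusted p = 0.00446; adjusted p = 0.546 with an estimated correlation), but not without post D (adjusted p 0.156), the profile with the highest share of these RNAs. In the hypoxia and glycolysis group, 16 of 21 were above 0 (median 1.28). EGLN3 rose, 20 did not pass, among them CA9, a hypoxia-induced carbonic anhydrase, at 3.38 (adjusted p 0.0525), and 10 rose when adjusted over the list alone, VEGFA and HK2 among them. The group lay above other genes (adjusted p = 0.0269; adjusted p = 0.613 with an estimated correlation), but not without pre A (0.0799), pre F (0.0533), post C (0.100) or post D (0.0611), nor without both profiles of C (0.0539). Of 10 pericyte genes, NOTCH3, a receptor of mural cells, rose 3.56 (adjusted p 0.0497), 9 did not pass, COX4I2 at 1.34 (adjusted p 0.0510) among them, and 7 rose when adjusted over the list alone. The pericyte group lay above other genes (adjusted p = 0.0318; adjusted p = 0.434 with an estimated correlation), but not without post F (0.0604) or with nuclei thinned to 1000 UMIs (0.123).

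Immediate early genes lay below other genes (adjusted p = 0.0144; adjusted p = 0.513 with an estimated correlation), but not without post D (0.0611). Their share of UMIs fell in A (0.0757% to 0.0547%) and F (0.0961% to 0.0668%). It rose in C (0.106% to 0.120%) and D (0.0848% to 0.122%), so the animals did not move alike. FOS fell by 1.52 on the log2 scale (adjusted p 0.0423), 16 of 17 did not pass, NR4A1 at −1.46 (adjusted p 0.0510) among them, and 3 fell when adjusted over the list alone. All 13 mitochondrially encoded genes were below 0 (median −0.64), none passed singly or when adjusted over the list alone, CYTB stood at −1.61 (adjusted p 0.0965) and ND4 at −0.81 (adjusted p 0.293), and the group lay below other genes (adjusted p = 0.0129; adjusted p = 0.528 with an estimated correlation). With animal as a block, the same 8 groups passed.

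The other groups did not pass camera. VCAN, a matrix proteoglycan, rose from 125 ± 16 to 328 ± 5.14 CPM (SD, n = 4 and 4; log2 fold change 1.39, adjusted p 0.0206), while 19 of 20 fibrillar collagen and matrix genes did not pass, LUM among them at 1.07 (adjusted p 0.0738), and 2 rose when adjusted over the list alone (group adjusted p 0.205). HGF, a growth factor of endothelium and muscle progenitors, rose from 34.2 ± 13.2 to 267 ± 147 CPM (log2 fold change 2.96, adjusted p 0.0232). ANGPTL4 rose 2.44 (adjusted p 0.0457), and 15 of 17 angiogenic genes did not pass; adjusted over the list alone, 7 rose and 3 fell (group adjusted p 0.180). None of 28 myogenic genes passed, with TNNT3 at 2.51 (adjusted p 0.0834) and MYBPH at 2.70 (adjusted p 0.0837); their median was −0.33 and their mean −0.11, while the test pointed up (adjusted p 0.782). None of 19 matrix remodelling enzymes passed, ADAMTS5 stood at 2.08 (adjusted p 0.0598) and MMP1, a collagenase, at 4.21 (adjusted p 0.0643), and adjusted over the list alone 4 rose and 2 fell (group 0.339). TGF beta response genes (17, none passed, SMAD7 at 1.40 with adjusted p 0.0557, median 0.13, mean −0.003, group 0.782; adjusted over the list alone 3 rose and 2 fell) and p53 and senescence genes (15, none passed, TP53INP1 at 1.42 with adjusted p 0.0527 and IGFBP3 at 3.53 with 0.0580, group 0.205; adjusted over the list alone 5 rose and 2 fell) did not pass. Neither did the interferon genes (16, none passed; IFIH1 at 1.51 with adjusted p 0.0851, MX2 at 2.51 with 0.0903; group 0.356), with none passing when adjusted over the list alone. PSAT1, which fell, was the only one of 14 stress-response genes to pass, and ASNS stood at −1.96 (adjusted p 0.0703). Adjusted over the list alone, both PSAT1 and ASNS fell. The group's median of 0.24 and mean of −0.19 differ in sign, with the test pointing down (0.507).

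No group of markers of other cell types passed camera. Endothelial genes (10, none passed) stood at a median of 0.74, with TEK at 2.01 (adjusted p 0.0632; 0.664 ± 0.0555 against 0.160 ± 0.0781 CPM) and TIE1 at 1.12 (adjusted p 0.172), group 0.102. Immune genes (8, none passed) included FCER1G at 1.43 (adjusted p 0.0955) and CD74 at 2.69 (adjusted p 0.140), group 0.180. Epithelial genes (3, none passed) included CDH1 at 2.15 (adjusted p 0.0885) and TP63 at 2.12 (adjusted p 0.107), group 0.102. Schwann and neural genes (5, none passed) included GFRA3 at −1.93 (adjusted p 0.100), group 0.624. LPL, an enzyme that releases fatty acids from lipoproteins, rose 3.70 (adjusted p 0.0280) and CIDEC of lipid droplets rose 3.33 (adjusted p 0.0478), to 10.7 ± 6.88 and 5.97 ± 5.49 CPM, in an adipocyte group of 4 (0.309). Without both profiles of C the immune (0.0184) and interferon (0.0184) groups passed camera, and the immune group also passed without pre A (0.0391) or pre C (0.0284).

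The share of nuclei with at least 2 UMIs of the proliferation genes, each nucleus thinned to 1000 UMIs, was 54.2% ± 10.4 before and 25.9% ± 13.5 after the bioreactor (SD, n = 4 and 4). It was 51.2%, 41.5%, 58.4% and 65.8% in pre A, C, D and F and 33.5%, 7.53%, 24.4% and 38.2% in the post profiles, lower in 4 of 4 animals (2-sided exact permutation p 0.0286, the smallest that 4 against 4 can give). Permuted within animals the exact p was 0.125, the smallest that 4 pairs can give. With at least 1 UMI it was 0.0857, and without pre D, pre F, post C or post D it was 0.0571. Free RNA can add to such shares, and how much it added stays open. In nuclei that resembled differentiating muscle, pooled over animals, the share was 25.1% before (387 nuclei) and 17.2% after (204 nuclei). These nuclei give no floor for free RNA, because 293 of the 387 came from pre C, where a finer clustering left 41 in this class and formed a cluster of 249 nuclei with MYF5 and NES, genes of myogenic progenitors, among its leading genes. The share with UMIs of the myogenic genes, chosen after the values were seen, was 16.7% ± 12.7 before and 17.4% ± 6.80 after (exact permutation p 0.914).

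**Figure D2:**
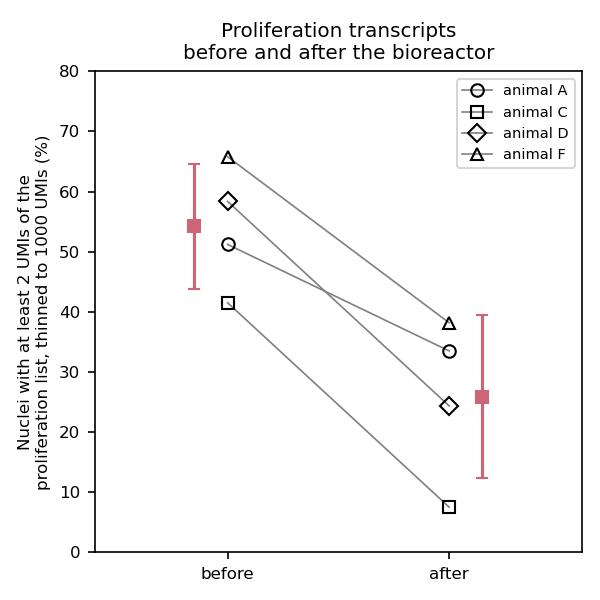
Percent of nuclei with at least 2 UMIs of the proliferation genes at 1000 UMIs per nucleus, before and after the bioreactor, with a line per animal and means ± SD beside. All 4 lines fall, from 54.2% ± 10.4 to 25.9% ± 13.5.

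Joint clustering of 34339 nuclei gave 15 clusters, 2 of which met the marker rule, and 91.5% of nuclei lay in the other 13. A cluster led by MYH3, NEB, CHRNA1, ACTC1, ACTA1 and MYOG, genes of newly formed muscle fibres, held 595 nuclei. It took up 1.40%, 10.7%, 0.121% and 0.0255% of the pre nuclei of A, C, D and F and 2.27%, 2.31%, 0.425% and 0.217% of the post nuclei. The means were 3.07% ± 5.15 and 1.31% ± 1.14 (SD, n = 4 and 4; exact permutation p 0.886; higher after in 3 of 4 animals). The direction turned at a finer clustering, at which pre C held 1.5% and the means were 0.762% and 1.31% (exact permutation p 0.486). It also turned without pre C (0.516% against 1.31%, exact permutation p 0.286). A cycling cluster with MYOCD, SST and TOP2A among its leading genes held 2334 nuclei, 16.8% and 15.6% of pre D and pre F, 6.61% of post F, at most 0.132% of pre A, pre C and post A, and 0 nuclei of post C and post D, where exact 95% limits allow 0.0670% and 0.261%. Its means were 8.15% ± 9.29 before and 1.68% ± 3.28 after (exact permutation p 0.2, adjusted 0.4). Post F, which gave 122 of its 126 post nuclei, shared a pool with pre D. The 126 nuclei had a median of 9660 UMIs, against 10636 in the pre nuclei of this cluster and 3949.5 in post nuclei outside the named clusters. Whether some were pre D nuclei counted as post F was not tested. At the finer clustering nuclei of cycling clusters also made up 22.4% of pre A, and the means were 13.8% ± 9.55 and 1.84% ± 3.26 (exact permutation p 0.0857). These shares leave out a further cluster of 1459 nuclei there, with 1158 of pre F and 292 of pre D. It had 7 cycling markers raised but none among its 10 highest genes, so it was not named. Of the 15 clusters of the joint clustering, 11 had more than 80% of their nuclei from 1 profile.

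The spatial comparison asks how grafts recovered after implantation differed from native oesophagus, with 6 graft and 4 native sections. Skeletal muscle RNA was scarce in 5 of the 6 grafts. PDK4, a kinase that blocks pyruvate oxidation and is high in muscle, fell from 232 ± 148 to 2.82 ± 2.16 CPM, ATP2A2, the calcium pump of slow and cardiac muscle, from 876 ± 325 to 138 ± 119, and MYLK2, the myosin light chain kinase of skeletal muscle, from 327 ± 162 to 15.1 ± 28.2. Genes of wound matrix rose: SFRP2, a Wnt modulator secreted by fibroblasts, from 34.6 ± 5.32 to 416 ± 344 CPM, CCN2, connective tissue growth factor, from 24.1 ± 8.82 to 283 ± 231, and THBS2, a thrombospondin, from 33.6 ± 8.31 to 279 ± 201. KRT17, a keratin induced in wounded epithelium whose counts are uncertain where reads could belong to related keratins, rose from 1.86 ± 1.49 to 173 ± 202 CPM. RET and PRPH, genes of enteric neurons, fell from 3.77 ± 1.22 to 0.531 ± 0.259 and from 11.1 ± 6.31 to 0.856 ± 0.470.

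edgeR called 715 of 12196 genes, 374 higher and 341 lower in grafts. An unadjusted p under 0.05 was found for 3110, and 1012 did not overlap between the groups, where chance alone gives 0.952% of genes. The largest rises were KRT17 (log2 fold change 6.52 ± 1.47 SE, adjusted p 0.0338), FOSL1 (5.07 ± 0.93, adjusted p 0.0220) and JUNB (3.61 ± 0.52, adjusted p 0.0122), both parts of the AP-1 transcription factor. After them came SFRP2, CCN2, CCL2, which attracts monocytes, PLAU, TNC, NOCT and THBS2, at 3.59 to 3.06 and adjusted p of 0.0188 to 0.0475. The largest falls were PDK4 (−6.30 ± 0.68, adjusted p 0.00391), MYLK2 (−4.41 ± 1.05, adjusted p 0.0400) and JPH1 (−4.08 ± 1.07, adjusted p 0.0492), which anchors the muscle calcium store. Among the next were MLF1, TMEM52, PI15, PRXL2B, ATP2A2 and TMOD1, which caps thin filaments, at −3.41 to −2.65 and adjusted p of 0.00985 to 0.0444. The gene annotation came in 2 versions, 1 for 4 sections (the F and C grafts, native C and the pre-implant section) and 1 for 7. With this version as a covariate edgeR called 1757 genes, 860 higher and 897 lower. Among native sections the version cannot be told apart from minipig against domestic pig, so this covariate does not isolate the annotation. DESeq2 called 1590. Without native 1, 2, 3 or C the edgeR count was 15, 17, 229 or 286, without the D, E or B graft 122, 268 or 333, and without the C graft 1696. It was 415 with only spots of at least 500 UMIs, and 128 without the shallow E graft and native C together. The domestic pigs stand only among the native sections, so breed and implantation cannot be told apart except in animal C, which has 1 section of each.

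All 22 mature skeletal muscle genes were below 0 (median log2 fold change −3.21) and none passed singly or when adjusted over the list alone, with CASQ1 at −3.40 (adjusted p 0.108) and ENO3 at −3.26 (adjusted p 0.135). The group lay below other genes (adjusted p = 6.9e-13; adjusted p = 0.386 with an estimated correlation). In the regenerating muscle and satellite cell group, MYOD1, which commits cells to muscle, fell by 3.61 on the log2 scale (adjusted p 0.0465), RUNX1, a transcription factor also active in blood cells, rose 2.91 (adjusted p 0.0239), and 14 of 16 did not pass. Adjusted over the list alone 1 rose and 3 fell, and the group lay below other genes (adjusted p = 1.07e-04; adjusted p = 0.442 with an estimated correlation). The muscle genes took up 8.25%, 9.48%, 3.76% and 9.42% of all UMIs in native 1, 2, 3 and C, against 0.0151%, 0.0243%, 0.346%, 0.00820% and 0.205% in the D, E, F, A and B grafts and 5.05% in the C graft. Spots with at least 2% of UMIs from these genes made up 74.2% ± 12.3 of native and 11.5% ± 22.4 of graft spots (SD, n = 4 and 6), with 56.7% in the C graft, 8.21% in F, 4.15% in B and 0% in D, E and A. The share of such spots was lower in 6 of 6 grafts than in every native section (2-sided exact permutation p 0.00476, the smallest possible, adjusted 0.0571 over 12 tests). At a threshold of 1% of UMIs it was lower in 5 of 6, with 64.5% in the C graft and 62.4% in native 3 (exact permutation p 0.00952, adjusted 0.114). Mitochondrially encoded genes moved with them. ND4L, ND5 and ND4 fell (ND4L −2.44, adjusted p 0.0269; ND5 −2.42, adjusted p 0.0391), 10 of 13 did not pass, 11 fell when adjusted over the list alone, and the group lay below other genes (adjusted p = 1.6e-08; adjusted p = 0.386 with an estimated correlation).

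Smooth muscle genes did not pass as a group (adjusted p 0.107). ACTA2, smooth muscle actin, rose from 463 ± 36.6 to 1172 ± 211 CPM (log2 fold change 1.34, adjusted p 0.0220), and the other 12 did not pass, TAGLN among them at 1.5 (adjusted p 0.0846). Relative to the skeletal muscle genes, the log2 ratio of smooth muscle UMIs was 3.73 ± 2.85 in grafts and −3.03 ± 1.01 in native sections (SD, n = 6 and 4), higher in 6 of 6 grafts (exact permutation p 0.00952, adjusted 0.0333 over 7 ratios, and 0.0333 permuted within annotation versions). Less skeletal muscle RNA alone raises this ratio, so it does not by itself show more smooth muscle RNA. The smooth muscle group passed camera without the D graft (0.0333), native 3 (0.0276) or native C (0.0385), and without the E graft and native C together (0.0163). Spots with at least 2% of UMIs from smooth muscle genes made up 29.5% of graft and 16% of native spots (exact permutation p 0.324), and those with differentiated epithelium 35.0% and 22.8% (exact permutation p 0.352), with 0.945% in the A graft. Collagen, endothelial and Schwann shares inside muscle or epithelium spots did not pass in any of the other 9 spot tests (lowest exact permutation p 0.0571, adjusted 0.343).

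Genes of fibrosis and wound response were higher. Of 22, 8 rose (CCN2, SFRP2, TIMP1, ADAM12, MMP2, TNC, MMP14 and CTHRC1), 14 did not pass, 13 rose when adjusted over the list alone, and the median was 1.87. The group lay above other genes (adjusted p = 6.5e-06; adjusted p = 0.579 with an estimated correlation). Among fibrillar collagen and matrix genes THBS2 rose, 17 of 18 did not pass, COL12A1 at 1.57 (adjusted p 0.0571) among them, and 2 rose when adjusted over the list alone. That group lay above other genes (adjusted p = 0.0399; adjusted p = 0.719 with an estimated correlation), but not without the A graft (0.314), native 1 (0.0714) or native C (0.181), nor without the E graft and native C together (0.176). Within sections, the log2 ratio of fibrosis to collagen UMIs was −2.73 ± 0.58 in grafts and −3.99 ± 0.20 in native sections (SD, n = 6 and 4), higher in 6 of 6 grafts (exact permutation p 0.00476, the smallest possible, adjusted 0.0333, and 0.0333 permuted within annotation versions). Both ratio calls were lost with the 6-month grafts alone (adjusted 0.0667) and without the D, E, F, A or B graft (0.0556 each) or native 1, 2 or C (0.0833 each), where the ratios kept their direction. Fewer sections give fewer labelings and a higher smallest possible p, so these losses alone do not show weaker ratios. The other ratios did not pass: regenerating to mature muscle −1.69 ± 1.76 against −3.96 ± 0.45 (exact permutation p 0.0333, adjusted 0.0778), COL3A1 to COL1A1 −0.22 ± 0.55 against 0.48 ± 0.30 (0.0667, adjusted 0.117), differentiated to basal epithelium 1.70 against 2.16 (0.181) and MYH11 to ACTA2 −0.71 against 0.45 (0.2). The share of MYH7 among the adult myosin genes cannot be compared, as the D and A grafts held 0 and 1 UMIs of these genes.

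**Figure D3:**
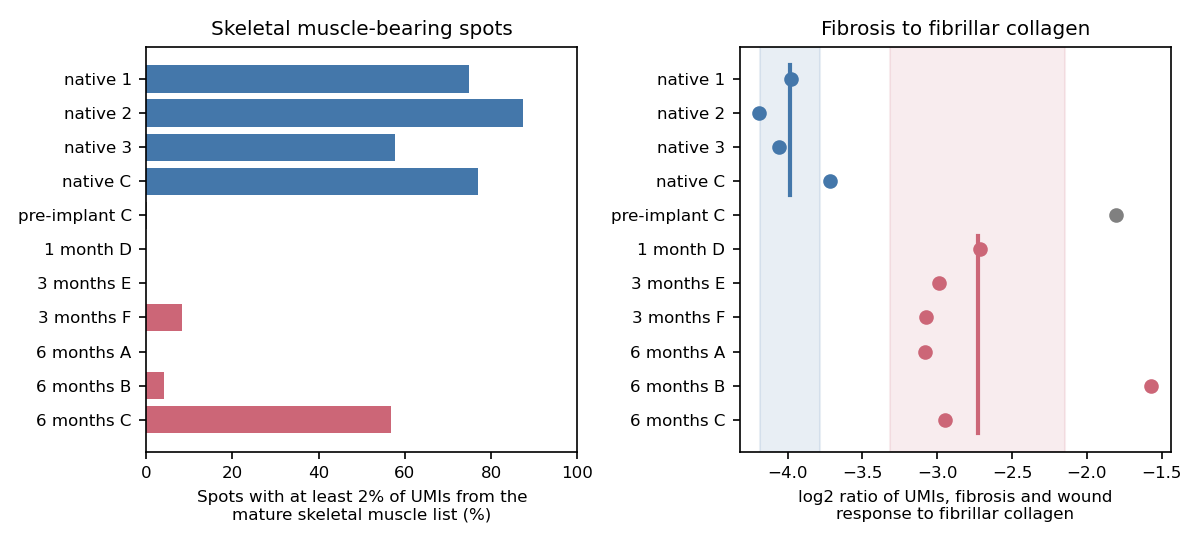
Percent of spots with at least 2% of UMIs from mature skeletal muscle genes (bars) and log2 ratio of fibrosis to fibrillar collagen UMIs (points) in each section, native in blue, grafts in red and the pre-implant section in grey, with lines at the means and bands of ± SD for native sections and grafts. The 6 grafts lie above every native section in the ratio (−2.73 ± 0.58 against −3.99 ± 0.20), and the C graft has the most muscle-bearing spots of the grafts (56.7%).

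Enteric neuron genes were lower. RET, PRPH, VIP, NEFL, GAP43 and TUBB3 fell, 4 of 10 did not pass, 9 fell when adjusted over the list alone and the median was −2.76. RET, a receptor needed by enteric neurons, stood at −2.79 (adjusted p 0.00985) and PRPH, a neuronal filament, at −3.70 (adjusted p 0.00985). The group lay below other genes (adjusted p = 5.7e-09; adjusted p = 0.217 with an estimated correlation). Schwann and glia genes did not pass (adjusted p 0.123; 0.0110 without the D graft), although L1CAM, an adhesion protein of axons and glia, rose 1.16 (adjusted p 0.0454), with 10 of 11 not passing, GFAP among them at 1.5 (adjusted p 0.0541), and 3 rising when adjusted over the list alone. Genes of interstitial cells of Cajal, the pacemakers of gut muscle, did not pass (3 tested; ETV1 −0.47 and ANO1 −0.35 with adjusted p 0.565 and 0.627; group 0.603).

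Among immune genes, POU2AF1 and MZB1 of B and plasma cells rose 5.21 and 3.24 on the log2 scale (adjusted p 0.0264 and 0.0338), DERL3 rose too, 4 of 7 did not pass and 5 rose when adjusted over the list alone. That group lay above other genes (adjusted p = 8.4e-04; adjusted p = 0.386 with an estimated correlation). Among genes of neutrophils and acute inflammation, IL6, a cytokine of acute inflammation, and CXCL2, which attracts neutrophils, rose 5.0 and 3.01 (adjusted p 0.0292 and 0.0301), CSF3R rose too, 5 of 8 did not pass and 4 rose when adjusted over the list alone. This group lay above other genes (adjusted p = 0.0190; adjusted p = 0.386 with an estimated correlation), but not without the E (0.0658) or B (0.155) graft. CD68 of macrophage lysosomes rose 1.75 (adjusted p 0.0338), 14 of 15 macrophage genes did not pass, CTSS at 1.37 (adjusted p 0.0514) among them, and 4 rose when adjusted over the list alone. The macrophage group lay above other genes (adjusted p = 0.0190; adjusted p = 0.710 with an estimated correlation), but not without the A graft (0.160) or native C (0.0833). Genes of T and NK cells (9, none passed; CD2 0.54 and GZMA −1.12, adjusted p 0.389 and 0.400; group 0.972) and mast cells (3, none passed; GATA2 0.85 and MS4A2 0.67, adjusted p 0.386 and 0.475; group 0.502) did not pass.

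RUNX2 and SOX9, transcription factors of bone and cartilage, rose 3.22 and 1.93 (adjusted p 0.0188 and 0.0316) at levels of 5.73 ± 3.40 and 4.60 ± 1.67 CPM. The other 3 tested of this group did not pass, 3 rose when adjusted over the list alone, and the group lay above other genes (adjusted p = 0.0312; adjusted p = 0.386 with an estimated correlation), but not without the A (0.0556) or C (0.0704) graft or with the annotation version as a covariate (0.0543). Of the proliferation genes, HMGB2, a chromatin protein, fell by 1.01 (adjusted p 0.0486), 18 of 19 did not pass, PCNA at −0.62 (adjusted p 0.0514) among them, and 2 fell when adjusted over the list alone; the group lay below other genes (adjusted p = 0.00567; adjusted p = 0.694 with an estimated correlation). VWF of vessel walls rose 2.51 (adjusted p 0.0447), 13 of 14 endothelial genes did not pass, ROBO4 at 1.47 (adjusted p 0.129) among them, and 1 rose when adjusted over the list alone. The endothelial group did not pass (0.0655), but passed without the E (0.0454), F (0.0125) or C (0.0277) graft, without native 2 (0.00686) or with the annotation version as a covariate (0.00990). LPL fell by 1.97 (adjusted p 0.0390) in an adipocyte group of 6 in which SCD stood at 0.79 (adjusted p 0.275), with median 0.11, mean −0.27 and adjusted p 0.303. ITGB4, a hemidesmosome integrin of basal epithelium, rose 1.26 (adjusted p 0.0338), and the other 10 basal genes did not pass, LAMB3 at 1.78 (adjusted p 0.183) among them (group 0.603).

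Differentiated epithelium (16, none passed; TGM3 1.44 and ECM1 0.49, adjusted p 0.324 and 0.398) had a median of 0.38 while its test pointed down (0.745), and up without the A graft (0.0407). Lymphatic genes (7, none passed; PDPN 1.35 and TFF3 −3.25, adjusted p 0.0915 and 0.101) had a median of 0.18 and a mean of −0.17 (group 0.610; adjusted over the list alone 1 rose and 1 fell). Submucosal gland genes (10, none passed; BPIFA1 3.29 and KRT19 0.86, adjusted p 0.144 and 0.357; group 0.901) did not pass. Blood genes (3, none passed; HBM −1.19 and HBB −1.92, adjusted p 0.233 and 0.255) did not pass as a group (0.107), but passed without the D graft (0.0306), native C (0.0160) or the E graft and native C together (0.0163). As shares of all UMIs, none of the 23 groups passed (lowest adjusted p 0.0939, shared by 7 groups with exact permutation p of 0.00952 to 0.0286, among them skeletal muscle at a mean log2 percent of −3.30 ± 3.49 in 6 grafts against 2.86 ± 0.64 in 4 native sections). Without the C graft 5 passed (adjusted 0.0365 each), mature and regenerating skeletal muscle, enteric neurons and mitochondrially encoded genes lower and fibrosis higher. The deposited Moran's I, a score of how strongly a gene clusters in space, gave no group past the threshold. Enteric neurons had the lowest adjusted value, with a median of 0.0109 ± 0.0144 in grafts and 0.101 ± 0.0750 in native sections (SD, n = 6 and 4; exact permutation p 0.0333, adjusted 0.367), and neutrophil genes had 0.0488 ± 0.0207 and 0.0177 ± 0.00550 (exact permutation p 0.0286, adjusted 0.367).

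**Figure D4:**
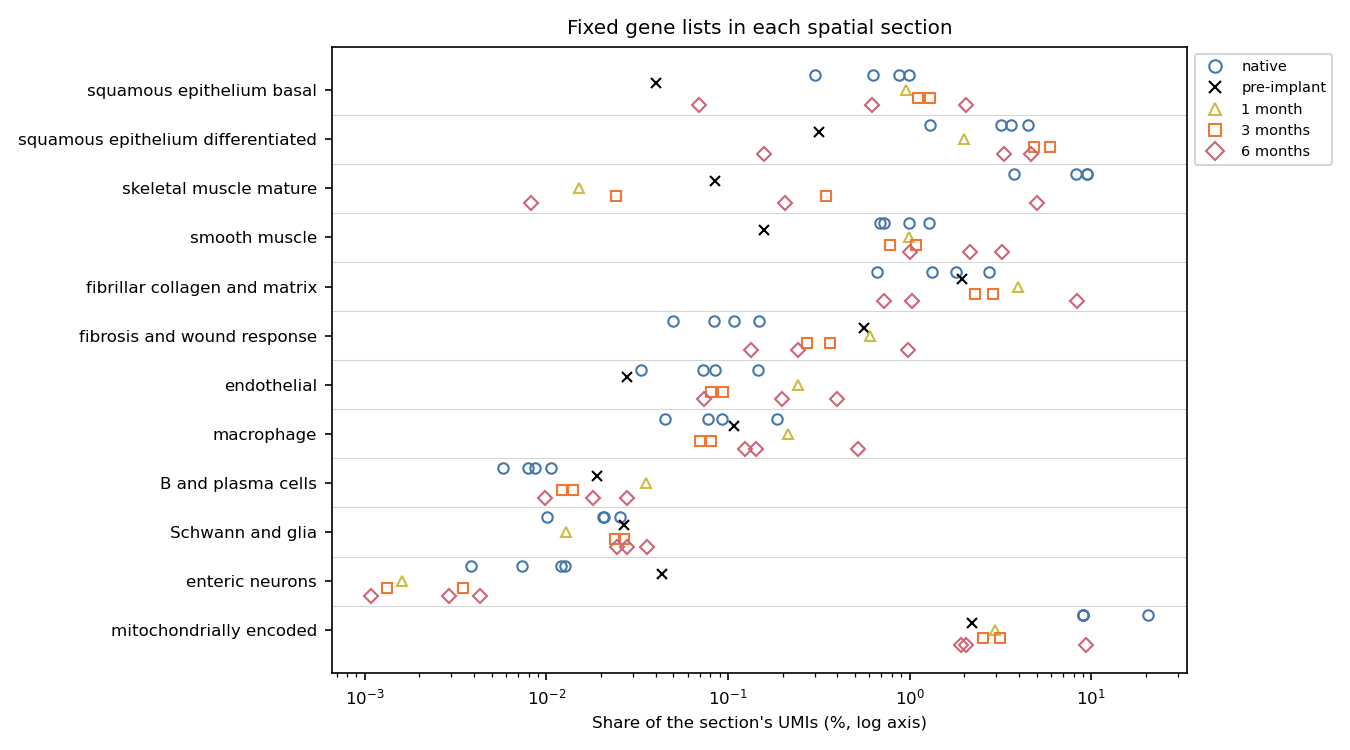
Share of UMIs (percent, log axis) of selected gene groups in each section, with points by section group. Fibrosis genes lie higher in 5 of 6 grafts than in every native section, and enteric neuron genes lower in 5 of 6, with the pre-implant section shown beside them.

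At 6 months the grafts of A, B and C showed the AP-1 gene FOSL1 at 55.3 ± 65.0 CPM against 1.09 ± 0.419 in native sections (SD, n = 3 and 4; log2 fold change 5.61, adjusted p 0.0451). CCL2 rose 4.14 (adjusted p 0.0451), JUNB 4.02 (adjusted p 0.0326), CCN2 3.69 (adjusted p 0.0498) and SPP1, the secreted bone and macrophage protein osteopontin, 3.56 (adjusted p 0.0428). PDK4 fell by 5.87, with adjusted p 0.0451, and PI15, SERHL2, BBIP1 and HMGB2 fell by 3.03, 2.32, 1.62 and 1.37, with adjusted p 0.0498. edgeR called 133 of 12989 genes, 107 higher and 26 lower, with 2907 at an unadjusted p under 0.05, while DESeq2 called 1196. The edgeR count was 1 without the E, F or B graft or native 1, 2 or 3, 13 without A, 58 without native C, 2156 without C, 684 with the annotation version as a covariate and 11 with only spots of at least 500 UMIs. It was 84 with DESeq2's size factors, 70 without the 20 most abundant genes, 82 without mitochondrially encoded genes and 12 without the E graft and native C together.

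At 3 months, with E and F against 4 native sections, edgeR called 0 of 12989 genes, with 1982 at an unadjusted p under 0.05, while DESeq2 called 606. The edgeR count was 68 with the annotation version as a covariate, 233 without the C graft, 51 without A, 17 without native C, 2 without B and 1 without native 3. Between 6 and 3 months edgeR called 0, with 1136 at an unadjusted p under 0.05, DESeq2 called 47, and edgeR called 1 without the A graft. With month as a slope over the 6 grafts edgeR called 0, with 534 at an unadjusted p under 0.05. In simulated data of these sizes the test recovered 18% of 4-fold changes at 6 months, 2% at 3 months and 0% between 6 and 3 months.

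In the single pre-implant graft, MMP1, a collagenase, stood at 277 CPM (Poisson 95% interval 269 to 287) against a native mean of 0.0820, CHI3L1, a secreted glycoprotein of inflamed tissue, at 11810 against 8.65, and TRPA1 at 109 against 0.0430. NAGS, a urea cycle enzyme, stood at 106 against 0.0400, and the hormone SST at 61.3 where the native sections held 0 UMIs. The keratin KRT5 and the cornified envelope gene CRNN had 0 UMIs, at least 4923-fold and 4413-fold lower than native at a floor of 3 counts. KRT4 had 3 UMIs, SPRP 2 and CNFN 1. Differentiated epithelium genes as a group took up 0.316% of UMIs (Wilson 95% interval 0.313 to 0.319). Of the 41568 UMIs of this group, KRT4, CNFN and CRNN gave only 3, 1 and 0. The share thus came from other members of the group and does not by itself show differentiated epithelium. Skeletal muscle genes made up 0.0853% of the section's UMIs (Wilson 95% interval 0.0838 to 0.0869) and fibrosis genes 0.559% (0.555 to 0.563), and the section's log2 ratio of fibrosis to collagen UMIs was −1.80. Its ratio of regenerating to mature muscle UMIs was −0.12 and that of MYH11 to ACTA2 −6.91.

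The single 1-month graft, of D, also held MMP1, at 49.5 CPM (43.4 to 56.2), KRT17 at 412 against a native mean of 1.66, and the mesothelial transcription factor WT1 at 16.2 against 0.0550. CST9L and PADI3 stood at 24.2 and 14.1 CPM against 0.125 and 0.0820. Genes of muscle fibres were nearly absent. The slow myosin MYH7 had 0 UMIs, at least 6643-fold lower than native, COX8H and MYH8 had 0 as well, at least 2765-fold and 1633-fold lower, MYL2 had 1 UMI and TNNT3 3. Fibrillar collagen genes took up 3.97% of its UMIs (Wilson 95% interval 3.95 to 3.98), endothelial genes 0.244% (0.240 to 0.249) and skeletal muscle genes 0.0151% (0.0140 to 0.0162). Such groups of 1 section have no replicate check, and these intervals and floors cover counting error only.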

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

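The tests of sequencing depth, of an exchange with a native section and of host muscle in the C graft, the fibrosis to collagen test and the counts of other splits were chosen only after the results they test were seen. A result stands here when 1 sample lay far from the other values of its group by Dixon's test, or when the pre-implant section, which enters no comparison, exceeded every native section. Of 360 groups of 4 to 10 values examined, 39 were marked in this way, and chance marks about 1 in 20, here 18.

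The 6-month graft of animal C lay far from the other 5 grafts in muscle RNA. Mature skeletal muscle genes took up 5.05% of its UMIs, regenerating muscle genes 0.512% and mitochondrially encoded genes 9.32%, and 56.7% of its spots bore skeletal muscle RNA. Its log2 CPM (with 0.5 added) was 6.19 for MYLK2, 6.25 for ND4L and 8.97 for ND5. Genes of interstitial cells of Cajal took up 0.0095% of its UMIs. A test of deeper sequencing of that section decides nothing: with every spot thinned to 500 UMIs 56.1% of spots still bore it, but a share of a spot's own UMIs hardly moves with thinning in any section. Its log2 ratio of fibrosis to collagen UMIs was −2.95, above the highest native value of −3.72 by more than the native SD of 0.20. This ratio goes against a full exchange with a native section. Its log2 ratio of COL3A1 to COL1A1, 0.60, lay within the native values of 0.19 to 0.75, however. A single ratio chosen after the result was seen does not exclude an exchange, least of all a partial one. Host muscle at the border of the section may account for the muscle RNA and cannot be told apart from muscle formed in the graft. The border was not mapped, and the ratio of regenerating to mature muscle UMIs, −3.30, only stands near the native values.

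For the genes changed between grafts and native sections, the C graft lay nearer native than the other grafts by a median of 0.78 for the genes that fell and by −0.66 for those that rose, under the bound of 1 set before, but 1 section excludes nothing. A test written after that looked inside muscle-bearing spots of the C, F and B grafts, with bounds set before its values were seen: the genes that fell stood below the muscle genes by −0.23, −0.08 and −0.28, so the C and F grafts met the bound set for less muscle as the source and the B graft met neither bound, and less muscle may account for the genes that fell. PDK4 goes against it, at 12.2, 16.3 and 0 CPM inside these spots against at least 31.7 in native sections, but it is 1 gene, and these spots also held less muscle RNA (9.62%, 5.96% and 4.91% of UMIs) than native ones (12.2%). For the genes that rose, the log2 ratio of fibrosis to collagen UMIs, which holds no mature muscle genes, differed by 1.26. Loss of muscle fibre RNA alone would leave this ratio as it was, so it goes against that source for the fibrosis genes. The ratio covers only these gene groups and not all genes that rose. It can also shift with the other tissue a section holds, so less muscle is not excluded. The native section of minipig C was nearer the graft mean than the domestic natives for 8.1% of the 715 genes (58). These genes were called with native C among the native sections, which selects against genes at which it lay with the grafts. A low share was therefore partly built in and decides nothing on breed. With 1 such section breed and implantation cannot be told apart. Of 100 splits of the 10 sections, 3 gave as many genes as the real split, itself included. Splits that set 2 grafts (F with C, and E with C) among the native sections gave 1970 and 783, more than the 715 of the real split. This points to a structure of the samples, and the count of genes does not exclude chance. For 6 months 1 of 35 splits, the real one, gave as many as 133, and the next gave 17. That is the best rank that 35 splits allow.

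Other sections stood apart in single values. Native C had the highest mitochondrially encoded share of the native sections (20.6%), and log2 CPM of 2.75 for ROBO4, −1.0 for GZMA and 7.58 for HBB. Native 3 had 1.16 for FOSL1 and 6.15 for TMEM52, and native 2 had 3.39 for LAMB3. The A graft had the highest shares of lymphatic genes (0.0772%) and macrophage genes (0.520%) among grafts, the D graft the highest share of blood genes (0.0576%), and the B graft the highest log2 ratio of fibrosis to collagen UMIs (−1.57).

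Among the nuclei, pre C had the highest median depth of the pre profiles (19347 UMIs), the highest share in the differentiating-muscle-like cluster (10.7%) and the highest share of UMIs from TGF beta response genes (0.430%). Its log2 CPM was 11.1 for CCN2, 8.96 for ND4 and −0.88 for TEK. Post D had the highest share of inflammatory RNAs (1.66%), log2 CPM of 11 for MMP1 and 1.26 for TP63, and 0.0007% of UMIs from epithelial genes. Post C had the highest shares of endothelial (0.0584%) and pericyte (0.0527%) genes among the post profiles. Post F, which shared a pool with pre D, had 6.61% of nuclei in the cycling cluster. Pre D stood apart in log2 CPM of STAC (5.16), ADAMTS20 (4.04) and IGFBP3 (1.70), and pre A in MCM5 (4.70) and TIE1 (−0.33).

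The pre-implant section exceeded every native section in the UMI shares of 7 gene groups. Fibrosis genes took up 0.559% against at most 0.149% in native sections, adipocyte genes 0.25% against 0.187%, T and NK cell genes 0.0449% against 0.0080%, and enteric neuron genes 0.0435% against 0.0127%. Schwann and glia genes took up 0.0269% against 0.0254%, B and plasma cell genes 0.0191% against 0.0106%, and cartilage and bone genes 0.0065% against 0.0020%.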

How the results depend on the processing

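The settings without both C profiles for the groups of the nuclei, without the E 3-month and C native sections, without mitochondrially encoded or skeletal muscle genes, with genotype-free donor calls, with the 10% highest doublet scores out, outside the named clusters, with Leiden 1.0 and the block, and the whole myogenic share were chosen only after the data were seen. No paired analysis was possible because the spatial groups share 1 animal number, C. Where values moved, the cause was not tested beyond fewer samples or genes where these were left out. Depth limits most the E graft and native C, in which 21.4% and 46.7% of spots reached 500 UMIs, and 2-fold changes were rarely recovered at these sizes in simulated data. No named gene reversed its direction in any setting; across named genes and settings, 2091 values kept their side of the threshold, 612 lost it and 88 gained it. For single groups in the camera and fry tests, 526 kept it, 59 lost it, 19 gained it and 25 changed direction, and for shares, ratios, spots and Moran's I 821 kept it, 20 lost it, 6 gained it and 56 changed direction. Within-cluster tests gave no value, as neither named cluster had 20 nuclei in every profile, and the cycling cluster was not named at 1000 UMIs. Scrublet marked too few doublets to act as an alternative, and its count of 340 says nothing on doublets. With animal as a block edgeR called 5 genes in the nuclei, 4 of them among the 347. At most 4 of the genes given as changed in the nuclei therefore kept their call, also where no blocked value stands beside them. For proliferating nuclei the block gave exact permutation p 0.125, and no other call of a comparison of groups changed with it.

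Genes in the nuclei (347) numbered 2628 with DESeq2, 5 with animal as replicate block, 4 with pool as a block, 44 without both profiles of C, 704 at up to 1% mitochondrially encoded UMIs and 609 outside the named clusters, and 1 to 1015 with 1 profile left out. Genes in grafts against native sections (715) numbered 1590 with DESeq2, 1757 with annotation batch, 415 in spots of at least 500 UMIs, 128 without the E and native C sections, and 15 to 1696 with 1 section left out. At 6 months (133) they numbered 1196, 684, 11 and 12 in the same settings, 84 with DESeq2 size factors, 70 without the 20 most abundant genes, 82 without mitochondrially encoded genes, and 1 to 2156 with 1 section left out. At 3 months (0) they numbered 606 with DESeq2, 68 with annotation batch and 0 to 233 with 1 section left out, and between 6 and 3 months (0) 47 with DESeq2 and 0 to 1.

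Groups called in the nuclei (8) numbered 0 with an estimated correlation, with or without the block, and 5 to 9 with 1 profile left out. Fry, which tests a group against no change and not against other genes, called 5. Without both profiles of C the adjusted p was 0.786 (down) for TGF beta response and 0.813 (down) for Schwann genes. With 1 profile left out it ranged over 0.143 to 0.870 for myogenic, 0.400 to 0.998 for TGF beta response, 0.0668 to 0.939 for interferon and 0.301 to 0.858 for stress-response genes, with changes of direction. Groups called in sections (11) numbered 0 with an estimated correlation, and fry called 4 against no change. T and NK cell genes turned up with annotation batch (0.806) and without E and native C (0.971), and gland genes down with annotation batch (0.948) and with fry (0.978). With 1 section left out, adjusted p ranged over 0.461 to 0.987 for T and NK cell, 0.344 to 0.991 for gland and 0.0407 to 0.933 for differentiated epithelium genes.

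UMI shares called (0 groups) numbered 0 to 5 with 1 section left out. Differences in mean log2 percent turned to −0.52 for basal epithelium and −0.83 for neutrophil genes with 6-month grafts only, and to 0.02 (0.0154) for Cajal, −0.02 (−0.0174) for T and NK cell and −0.26 for neutrophil genes without E and native C. With 1 section left out they ranged over −0.22 to 0.81 for basal (0.14), −0.71 to 0.45 for differentiated (−0.32), −0.27 to 0.01 (0.0125) for Cajal (−0.13), −0.18 to 0.51 (0.505) for T and NK cell (0.23), −0.24 to 0.97 for neutrophil (0.26) and −0.18 to 0.54 for adipocyte genes (0.16). Ratios called (2) numbered 0 with 6-month grafts only, 0 without E and native C, and 0 to 2 with 1 section left out.

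In spots, the collagen difference in skeletal muscle spots (0.0532 percent of UMIs) turned to −0.206 at 5% and −0.404 without E and native C, over −0.404 to 0.469 with 1 section left out. In smooth muscle spots collagen (0.288) turned to −0.340 at 5%, over −0.726 to 0.653, and endothelial genes (−0.0175) to 0.0435 at 1%, 0.0132 at 5% and 0.0370 thinned, over −0.0568 to 0.0569. Moran's I differences turned to −0.0119 for adipocyte genes without E and native C. With 1 section left out they ranged over −0.0289 to 0.0933 for smooth muscle, −0.0001 to 0.0155 for endothelial, −0.0922 to 0.0016 for gland, −0.0227 to 0.0223 for adipocyte, −0.0019 to 0.0051 for proliferation and −0.0240 to 0.0080 for cartilage genes.

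The difference for the differentiating-muscle-like cluster (−1.77 percent of nuclei) turned to 0.543 at Leiden 1.0 (exact permutation p 0.486), also with the replicate block (exact permutation p 0.125, the smallest possible), over −2.78 to 0.790 with 1 profile left out. For proliferating nuclei the difference of −28.3 had exact permutation p 0.125 with the replicate block, and −19.6 at 1 UMI had 0.0857, over −32.6 to −22.2 with 1 profile left out. The myogenic share (0.747) turned to −0.179 at 3 UMIs and −20.9 without thinning, over −2.41 to 7.00.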

Other observations

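The genes behind the pre-implant section's shares were looked up after the shares were seen, and the tests of splits, depth and preparation in the nuclei were also chosen only after the results were seen. In most of the groups that stood above native, a few genes made up the share. UCHL1, a ubiquitin hydrolase of neurons and of cultured cells, and TUBB3, a tubulin, made 72.8% and 25.1% of the enteric neuron UMIs. CCL5, a chemokine, made 99.4% of the T and NK cell UMIs, XBP1, a transcription factor of secretory cells, 86.2% of the B and plasma cell UMIs, complement factor CFD 91.3% of the adipocyte UMIs and PMP22 85.0% of the Schwann UMIs. SOX9 made 55.2%, SPP1 25.8% and RUNX2 16.3% of the cartilage and bone UMIs, MMP2 32.9% and LOXL2 22.0% of the fibrosis UMIs, and FN1 38.6% of the collagen and matrix UMIs. Of the regenerating muscle UMIs, ACTC1 made 30.1%, TNNT2 18.2% and the embryonic myosin MYH3 17.2%. In the grafts, SPP1 made 92.3% of the cartilage and bone UMIs in B and 85.8% in C, while ACAN, a cartilage proteoglycan, made 45.4% in A.

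Each post profile was led by its own genes in the clustering, in clusters that met no marker rule. The cluster with 97.5% of post C nuclei was led by EGLN3, CGNL1, ERO1A and VEGFA, the last an angiogenic factor induced in hypoxia. That with 90.2% of post A nuclei was led by ATP10B, TRPA1, PRICKLE2 and PRR16. A cluster with 1197 post D nuclei was led by the matrix proteases MMP3 and MMP1 and the cytokines IL6, CSF3 and IL11, and one with 1255 post F nuclei by the growth factor IGF1 and the aggrecanase ADAMTS5. A cluster in which 5 markers of myogenic progenitors were raised held 24.3% of pre A, 1.74% of pre F, 1.06% of post D and 0.432% of pre D nuclei. MMP1 and TRPA1 were high in the pre-implant section (277 and 109 CPM). In the post profiles TRPA1 stood at 466 ± 439 CPM (SD, n = 4), and MMP1, which did not pass the test, at 113, 140 and 94.9 CPM in A, C and F and 2058 in D.

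A hypothesis is that the bioreactor itself changed the cells, and 3 technical explanations were set against it. Of all 35 splits of the profiles, 1, the real one, gave as many as 347 genes, and the highest other split gave 0. The profiles are paired by animal, however, and 8 of these splits part the 2 profiles of every animal, too few for a share under 5%; among these 8 too, the real split gave 347 and the highest other 0. The other splits keep both profiles of at least 1 animal together. With animal as a block edgeR called 5 genes. The test of fewer UMIs per nucleus does not exclude them as a source. With every nucleus thinned to 1000 UMIs, 89.8% of the called genes that could be tested (238 of 265) were still called. Thinning keeps the expected proportions of genes in each nucleus, however, and with them any part that is free RNA. Differences in how nuclei were obtained may account for the change, because 0 profiles cross preparation with condition, so flask and scaffold cannot be told apart from pellet and tissue section. Nuclei or free RNA exchanged within a pool may account for the likeness of profiles that shared one: the test planned for genes 20 times higher found 0 eligible genes, and its replacement with genes 3 times higher, set before the levels were seen, found the same-pool post profile above the same-animal one in 2 of 2 pools with enough genes, which a difference between libraries would also give.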
